A study of Mus musculus with 4 samples.

How the data were processed

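Total RNA of adult mouse cardiac endothelial cells was labelled with Cy3 and hybridised to Agilent 1-colour arrays, per the labels' protocols, with 1 array for each of 4 samples. The samples fall into 2 control and 2 G2-EC-KO samples by their titles, and the labels give replicate numbers 1 and 2 in each group without saying that the numbers pair samples. Per the file headers, the arrays are of design 014868, annotated on mm9, and the spots were quantified with Feature Extraction 10.7.3.1, while the submitters' processing notes name version 10.5. The 4 arrays lay on 1 slide and were read in 1 scan. The control arrays took positions 1 and 2 and the G2-EC-KO arrays positions 3 and 4, so position on the slide and group cannot be told apart.

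The scanner files hold spot intensity values on a linear scale that the authors deposited, which per the file headers were background-subtracted and detrended within each array and not normalized between arrays. Each array has 45018 spots, of which 43379 are not controls and carry 41174 probes. The median processed signal was 150 and 148 on the control arrays and 133 and 123 on the G2-EC-KO arrays, the 75th percentile was 1411, 1438, 1288 and 1181, and the median local background was 37, 39.5, 40.5 and 40. A deposited value table of the same arrays, with medians of 169, 166, 149 and 138.5, equals the median spot signal minus the median local background plus 16 in every row. Its scale is therefore linear and it is not centred. It was used as an alternative only, floored at 1 before log2.

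Control spots and spots flagged as outliers, 90, 101, 87 and 99 on the 4 arrays, were left out. The log2 of the processed signal was taken, the 75th percentile of each array was subtracted, and spots of the same probe were averaged. A probe was tested when it was well above background on at least 2 of the 4 arrays, whatever their group, which left 26894 probes, 25500 of them well above background on all 4. Where a probe was not well above background on either array of a group, the difference is given as a bound: the mean of the brighter group against the mean, per array, of the higher of the lowest signal well above background and the signal of the probe. The scanner files give accessions without gene symbols. Symbols were taken by accession from a RefSeq table of assembly GRCm38.p6, which matched 26933 of 41174 probes and left 14241 unnamed. No coordinates are given, since that assembly is not the one of the array annotation.

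Groups were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on group alone, two-sided, and Benjamini-Hochberg adjustment at 0.05 over all probes tested. The fit had 2 residual and 2.58 prior degrees of freedom, and the median SE of a log2 change was 0.136. An exact permutation test of 2 against 2 cannot give a two-sided p below 0.333, so limma's values are given. The design, the tests, the gene lists and the rule for named genes were fixed before the data were examined. The 36 lists, 698 genes of which 677 have a probe, hold cell type markers and processes, and 8 genes were renamed through synonyms. They were tested with limma camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, on 1 probe per gene, that with the highest mean over all arrays. Benjamini-Hochberg adjustment was over the 36 lists, and 11 probes without a value on every array were left out of these tests.

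The rule named the GATA genes, up to 12 genes past the threshold in each direction or else the 5 with the smallest p as values only, members of the lists described, the cDNAs AK037972 and AK038629, and the members with the highest signal in the cell type lists weighed. Which lists without a call are described with examples was chosen after the values were seen, as was picking up to 4 cell cycle members and Lum by the adjustment over the list alone. The sex-linked probes and NM_018852 were also chosen after the values were seen.

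The tests were tested on simulated data with the spread of the real arrays, 20 simulations of 26883 probes with 200 changed. The probe test recovered 6.04% of 2-fold changes, 79.8% of 4-fold and 96.4% of 16-fold changes, with 6.5 false calls per simulation on average. Many planted changes make the adjusted threshold easier to pass. In the real data 1 probe passed, so these shares do not apply there. A log2 shift of 0.5 in the 31 genes of the cell cycle list was called in 20 of 20 simulations with the preset correlation and in 0 of 20 with the estimated one, and 0 simulations without a shift called a list. These simulations drew genes independently, which real genes are not. They therefore do not bound false calls of lists with correlated genes, nor give the power for such lists.

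Alternatives, all fixed before the data were examined, were normexp background correction with an offset of 50, quantile normalization, median centring, no filter on dim probes, a filter on all 4 arrays, the deposited value table, an intensity trend in eBayes, the replicate number as a block, leaving out each array, an adjusted p of 0.1, a log2 change of at least 1, and the other list tests. The scanner files used here have no mean signal column, so normexp used the median signal and the median background. The slide as a block was not fitted, since there is 1 slide.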

Results

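Gene expression was measured in endothelial cells isolated from adult mouse hearts, the cells that line the vessels and chambers of the heart. The labels give 2 control arrays, from wild type mice, and 2 arrays labelled G2-EC-KO, which they also call a Gata2 knock out. Each sample was hybridised to 1 Agilent 1-colour oligonucleotide array with 41174 non-control probes. The share of probes well above background was 63.8% and 65.0% on the control arrays and 65.1% and 66.5% on the G2-EC-KO arrays, and 0 spots were saturated. The number of arrays, 2 per group, limits the precision of every value. The labels do not say whether the replicates came from separate animals. Y-linked transcripts were well above background at 6 of 6 probes on control replicate 2 and at 0 on control replicate 1. This argues against a shared RNA source for the control arrays, and for the G2-EC-KO arrays the question stays open. The p-values therefore measure the spread between these samples, which may be technical in part. The one comparison of the design asks how the transcripts of cardiac endothelial cells differ between mice labelled G2-EC-KO and control mice. Gata2 is a zinc finger transcription factor of blood and endothelial cells. The title of the series speaks of secreted long non-coding RNAs.

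Gata2 was not lower in the arrays labelled G2-EC-KO. Its probe A_51_P516625 read 2.02 ± 0.22 (SD, n = 2) in control and 2.31 ± 0.21 (SD, n = 2) in G2-EC-KO, in log2 units above the 75th percentile of the array. The log2 change was 0.29 (SE 0.18, 95% confidence interval -0.17 to 0.76; limma, adjusted p = 0.586). The second probe, A_52_P233441, gave a log2 change of 0.17 (SE 0.14; limma, adjusted p = 0.653). Leaving out 1 array moved these between 0.14 and 0.45 and between 0.065 and 0.28. Neither the deleted part of the gene nor the position of the probes within it is given in the sources used here. A probe outside the deleted part checks nothing, so these values neither bear out nor contradict the labels. Every direction given for this comparison rests on the labels alone. Of the other GATA factors, Gata6, Gata4 and Gata3 were also measured and did not pass the threshold, with log2 changes of 0.30 (SE 0.15) at the brightest Gata6 probe, 0.023 (SE 0.12) at Gata4 probe A_52_P4201 and 0.11 (SE 0.21) at Gata3. The other Gata4 probe, A_51_P492355, gave -0.15 (SE 0.17), opposite in sign, and the other Gata6 probes gave 0.11 (SE 0.17) and 0.24 (SE 0.35). The brightest Gata6 probe moved between 0.13 and 0.46 when 1 array was left out. The signs of both Gata4 probes, of Gata3 and of the dimmer Gata6 probes turned when 1 of the arrays was left out. Probes for Gata1 and Gata5 were well above background on 0 arrays and were not tested.

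The clearest single difference was a transcript with no gene symbol, the cDNA AK038629. It was not well above background on either control array and was well above it on both G2-EC-KO arrays, where it read at least 7.49-fold higher (limma, adjusted p = 0.0431). A second cDNA, AK037972, was also well above background on the G2-EC-KO arrays alone, at least 42.0-fold higher than in control. It did not pass the threshold (limma, adjusted p = 0.387). These bounds hold for the processed signal, and with normexp background correction the fitted log2 changes were smaller, 2.09 for AK038629 and 3.96 for AK037972. The adjusted p of both rests on control signals that were not flagged as well above background. The signal of AK037972 on control replicate 1, -5.466, lay just above the lowest signal well above background on that array, -5.474. Both cDNAs were named before the data were examined, from knowledge of the study, so their place among the leading transcripts is not an unprompted finding. Large differences of this kind also occurred between the 2 control arrays, at genes chosen after their values were seen. Ifi202b read 2.78 on control replicate 1 and -6.20 on control replicate 2, and Slc15a2 read -7.59 and 1.15. The call for AK038629 was lost without a filter on dim probes (limma, adjusted p = 0.243), with an intensity trend in the variance (limma, adjusted p = 0.0700) and with the replicate block. It was also lost without control replicate 2, G2-EC-KO replicate 1 or G2-EC-KO replicate 2. Its fitted log2 change stayed between 4.86 and 5.13 when 1 array was left out. AK037972 passed with normexp background correction (adjusted p = 0.0387) and without control replicate 1 (adjusted p = 0.0155).

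**Figure D1:**
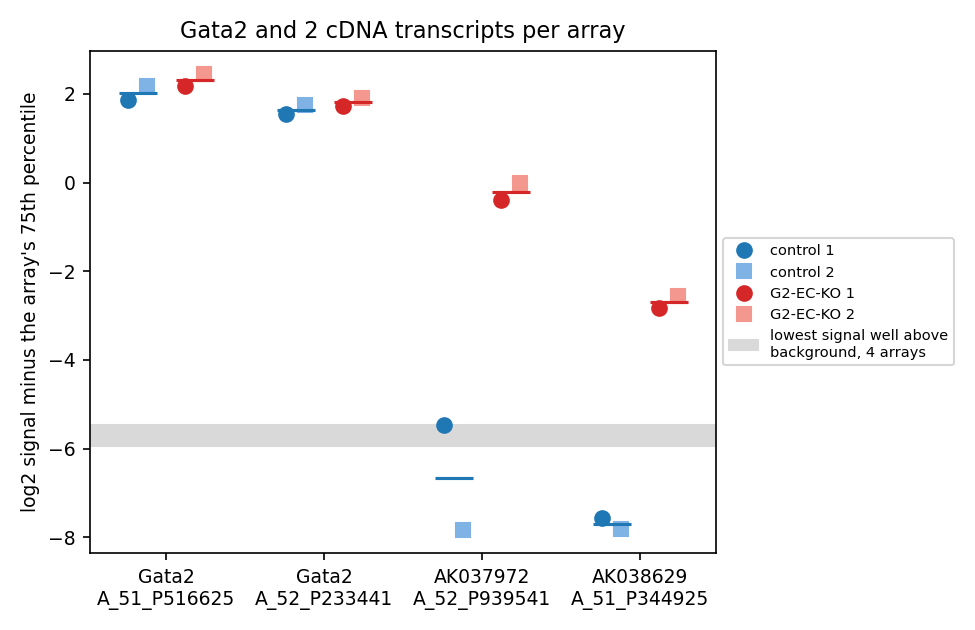
Level of both Gata2 probes and of the cDNAs AK037972 and AK038629 on each array, as log2 signal minus the 75th percentile of the array, with bars at the group means and a grey band over the lowest signals well above background on the 4 arrays. Gata2 lies between 1.86 and 2.46 on all arrays at probe A_51_P516625, while AK038629 reads -7.57 and -7.81 in control, not well above background, and -2.83 and -2.56 in G2-EC-KO.

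Across the 26894 probes tested, AK038629 was the 1 probe past an adjusted p of 0.05, with 1 probe higher and 0 lower. No gene with a symbol passed, 0 of 13628. With quantile normalization or median centring 1 probe was higher and 1 lower, the latter being NM_018852, a transcript with no symbol in the reference table that was chosen after its values were seen. It was not well above background on the G2-EC-KO arrays and at least 2.97-fold higher in control by the processed signal (limma, adjusted p = 0.0773), with a smaller fitted log2 change of -0.79 with normexp. At an unadjusted p under 0.05 the limma fit gave 2590 probes, 1317 higher and 1273 lower, against 1345 that chance would give. Among genes with a symbol, 971 were higher and 540 lower. Without control replicate 1 there were 1335 probes at that p, without control replicate 2 there were 1447, without G2-EC-KO replicate 1 there were 5591 and without G2-EC-KO replicate 2 there were 2182. The groups did not overlap at 46.4% of probes, against 33.3% by chance. Without ties, a probe is free of overlap in exactly 1 of the 3 groupings of the arrays into pairs. Some grouping must therefore reach 33.3% whatever the labels. Probes also vary together, and position on the slide follows the groups. Neither this share nor the count of 2590 probes shows by itself an effect of the labels.

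Since no named gene passed in either direction, those with the smallest p are given as values only. On the higher side these were Bmp3, a bone morphogenetic protein, the RIKEN transcript 4930503E14Rik, the glutamate receptor subunit Gria1, the formin Diaph3 and the DNA repair gene Brca1. All of them were not well above background in control, so that the difference is a bound on the processed signal, of at least 1.04-fold for Bmp3, 3.26-fold for the RIKEN transcript, 1.76-fold for Gria1 and 1.73-fold for Brca1. The control signals of Diaph3 lay above the lowest signal well above background, so that its 4.2-fold is the fitted value. With normexp the log2 change was 1.09 for Diaph3 and also smaller for the others, from 0.49 for Bmp3 to 1.53 for the RIKEN transcript. The smallest adjusted p among them was 0.136, for Bmp3. Further probes of Diaph3 and Brca1 that were well above background in both groups gave log2 changes of 1.17 (SE 0.18) and 1.15 (SE 0.21). On the lower side, Psd2 was not well above background in G2-EC-KO and at least 2.28-fold higher in control (adjusted p = 0.165), with a log2 change of -0.46 with normexp. The cGMP-dependent kinase gene Prkg2 had a log2 change of -1.03 (SE 0.12), the transcriptional corepressor gene Tle1 one of -1.08 (SE 0.13), Abi3bp one of -0.93 (SE 0.12) and the phospholipid flippase gene Atp8a1 one of -0.86 (SE 0.11), all with an adjusted p of 0.387. Probes disagreed for Abi3bp, where another gave 0.39, and for Atp8a1, where others gave -0.0045 and -0.50. With normexp the probes first named gave -0.68 for Prkg2, -1.05 for Tle1, -0.27 for Abi3bp and -0.44 for Atp8a1.

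Of 36 gene lists fixed before the data were examined, the cell cycle list stood farthest from the rest. Of its 31 measured genes, 29 were higher and 2 lower in G2-EC-KO, with a median log2 change of 1.09 (limma camera with a preset correlation, adjusted p = 7.67e-19). The correlation among its genes was estimated at 0.40, against the preset 0.01. With the estimated correlation the list did not pass (limma camera, p = 0.0999, adjusted p = 0.931), nor by limma fry (p = 0.0394, adjusted p = 0.709). Camera with an estimated correlation called a simulated log2 shift of 0.5 in this list in 0 of 20 simulations. The simulated genes were drawn independently, and the planted shift was smaller than the observed median. Power at the observed median and correlation was not simulated. These simulations therefore do not set aside that the list did not pass. Adjusted over the list alone, 25 genes were higher, and over all probes tested 0 passed. Since these genes vary together, the 25 are not separate findings. The examples with the smallest p were the mitotic kinase gene Aurkb, with a log2 change of 1.78 (SE 0.27), the topoisomerase gene Top2a, with 1.47 (SE 0.24), the replication helicase gene Mcm5, with 0.96 (SE 0.16), and the cyclin gene Ccne2, with 1.05 (SE 0.18), each with an adjusted p over the list alone of 0.0130. With normexp the log2 changes were 0.66 for Ccne2, 1.30 for Aurkb, 1.24 for Top2a and 0.91 for Mcm5. The G2-EC-KO arrays differed from each other in the genes of the list, with a median of 0.88 above the control mean on replicate 1 and 1.49 on replicate 2.

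**Figure D2:**
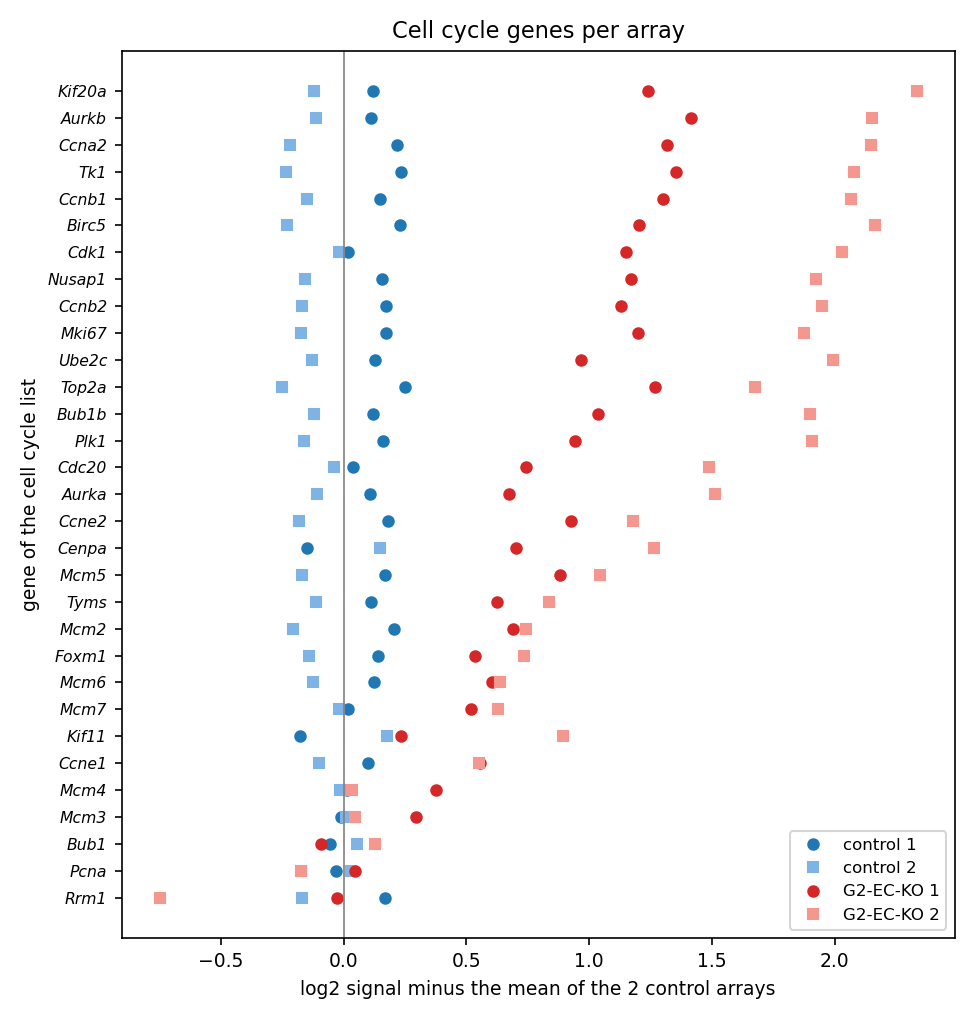
Each of the 31 measured genes of the cell cycle list on each array, as log2 signal minus the mean of the 2 control arrays, with genes ordered by their log2 change. In 29 genes the mean of the G2-EC-KO arrays lies above the control mean, and Rrm1 and Pcna lie below it.

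Markers of 3 other cell types, cardiomyocytes, macrophages and monocytes, and fibroblasts, were higher alongside the cell cycle genes, while those of pericytes and smooth muscle, lymphocytes, granulocytes, blood and platelets, and mesothelium and neural cells did not pass. These lists were also called in groupings of the arrays into pairs that mix the labels. The cardiomyocyte and macrophage lists were called in both such groupings. The fibroblast list was called where control replicate 1 was grouped with G2-EC-KO replicate 1. Their calls therefore do not single out the labelled grouping. Cardiomyocyte markers had a median log2 change of 0.31, with 23 of 24 genes higher (limma camera with a preset correlation, adjusted p = 0.00334; adjusted p = 0.931 with an estimated correlation). Macrophage and monocyte markers had a median of 0.34, with 17 of 18 higher (adjusted p = 0.00334), and fibroblast markers one of 0.19, with 16 of 18 higher (adjusted p = 0.00797). Both had an adjusted p of 0.931 by camera with an estimated correlation. The estimated correlations were 0.49 for cardiomyocyte, 0.58 for macrophage and monocyte and 0.35 for fibroblast markers, against the preset 0.01. Adjusted over the list alone, 1 marker passed among these lists, the fibroblast proteoglycan gene Lum, with a log2 change of 0.87 (SE 0.14; adjusted p over the list alone 0.0377). Values for members that did not pass were 0.49 (SE 0.17) for the natriuretic peptide gene Nppb, 0.61 (SE 0.23) for the myosin gene Myh7 and 0.34 (SE 0.12) for the myeloid adaptor gene Tyrobp. The chemokine receptor gene Ccr2 was not well above background in control and at least 1.5-fold higher in G2-EC-KO. The markers with the highest signal in each list did not pass, with log2 changes of 0.12 (SE 0.13) for Actc1, 0.36 (SE 0.20) for Myl2, 0.50 (SE 0.22) for Pf4, 0.15 (SE 0.24) for Lyz1, 0.086 (SE 0.15) for Gsn and 0.12 (SE 0.21) for Dcn, of which Lyz1, Gsn and Dcn changed sign when 1 of the arrays was left out. Leaving out 1 array also moved Myl2 between 0.12 and 0.59, Pf4 between 0.22 and 0.79, Actc1 between 0.011 and 0.23 and Myh7 between 0.30 and 0.92. The fibroblast call was lost without control replicate 1 (median 0.068, adjusted p = 0.272) and without G2-EC-KO replicate 2 (median 0.13, adjusted p = 0.0516), the macrophage call without control replicate 1 (median 0.095, adjusted p = 0.354) and without G2-EC-KO replicate 1 (median 0.32, adjusted p = 0.220), and the cardiomyocyte call without G2-EC-KO replicate 2 (median 0.044, adjusted p = 0.621). Other arrays left out raised the medians, to 0.65 for macrophage and monocyte markers and 0.37 for fibroblast markers without control replicate 2, and to 0.61 for cardiomyocyte markers without G2-EC-KO replicate 1.

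Genes of 2 housekeeping processes were also higher by small amounts. Oxidative phosphorylation, the respiratory chain and ATP synthase, had a median log2 change of 0.13, with 31 of 35 genes higher (limma camera with a preset correlation, adjusted p = 0.00334; adjusted p = 0.931 with an estimated correlation). Its members with the smallest p were Ndufb3, at 0.37 (SE 0.14), and Ndufa4, at 0.34 (SE 0.15), which moved between 0.19 and 0.49 when 1 array was left out. Cytosolic ribosomal proteins had a median of 0.076, with 40 of 46 higher (adjusted p = 0.0158; adjusted p = 0.931 with an estimated correlation), and included Rpl27, at 0.23 (SE 0.12), and Rplp1, at 0.20 (SE 0.11). Without control replicate 1 neither list passed, with medians of 0.091 (adjusted p = 0.124) and 0.040 (adjusted p = 0.477). The ribosomal list also lost its call with normexp (median 0.083, limma camera, adjusted p = 0.0943) and with quantile normalization (median 0.049, adjusted p = 0.270). Without G2-EC-KO replicate 1 it lost its call too, with a median of 0.085. The other groupings of the 4 arrays into pairs, which mix the labels, called 8 and 14 lists, more than the 6 of the labelled grouping. The cardiomyocyte and the macrophage and monocyte lists were called in both of them. The fibroblast list was called in the grouping of control replicate 1 with G2-EC-KO replicate 1. The ribosomal list was called in that of control replicate 1 with G2-EC-KO replicate 2. The cell cycle and oxidative phosphorylation lists were called in neither. For the cell cycle list the adjusted p was 0.723 and 0.0775 (limma camera with a preset correlation). In such groupings a difference between the labels widens the spread within each pair, which works against a call. Not being called there is therefore no support for these lists.

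Genes that mark endothelium itself did not shift as a group. The endothelial identity list had a median log2 change of 0.033, with 17 genes higher and 11 lower (limma camera, adjusted p = 0.998), and its members with the highest signal, the VEGF receptor gene Flt1 and the matrix glycoprotein gene Mmrn2, had log2 changes of 0.0066 (SE 0.11) and 0.033 (SE 0.13), whose sign turned with quantile normalization and when 1 of the arrays was left out. Its members with the smallest p were Plvap, a protein of endothelial diaphragms, at 0.43 (SE 0.11), and the nitric oxide synthase gene Nos3, at -0.50 (SE 0.14). The list of endothelial genes linked to GATA2 in the literature had a median of -0.12 (adjusted p = 0.373), where the receptor gene Tek had a log2 change of -0.24 (SE 0.11). Medians were -0.045 for arterial endothelium (adjusted p = 0.573), -0.036 for venous endothelium (adjusted p = 0.889), 0.13 for endocardium (adjusted p = 0.330) and -0.22 for lymphatic endothelium (adjusted p = 0.321). GATA family and partners had a median of 0.011 (adjusted p = 0.889). Leaving out 1 array moved the median of the genes linked to GATA2 between -0.20 and -0.00080, of arterial endothelium between -0.086 and -0.014, of venous endothelium between -0.32 and 0.056, of endocardium between -0.019 and 0.28, of lymphatic endothelium between -0.26 and 0.0063, of GATA family and partners between -0.12 and 0.038 and of endothelial identity between -0.035 and 0.083. Of these, endocardium passed as higher without G2-EC-KO replicate 2 (median 0.28) and lymphatic endothelium as lower without control replicate 1 (median -0.22).

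Among the lists that did not pass, antigen presentation by MHC class II came nearest to the threshold. It had a median log2 change of -0.32, with 8 of 9 genes lower (limma camera, adjusted p = 0.0577), where the invariant chain gene Cd74 gave -0.32 (SE 0.10) and H2-Ab1 gave -0.32 (SE 0.12). It passed with normexp, with the all-array filter on dim probes, with the deposited value table and without control replicate 2 or G2-EC-KO replicate 1. Its adjusted p was farther from the threshold without a filter on dim probes (0.224), without control replicate 1 (0.272) and without G2-EC-KO replicate 2 (0.243, median -0.12). The NOTCH pathway had a median of -0.078, with 14 of 17 genes lower (adjusted p = 0.155), and the smallest p of all lists by limma fry (adjusted p = 0.0992), and passed by camera with normexp. Its ligand gene Dll1 gave -0.33 (SE 0.12) and the receptor gene Notch1 gave -0.48 (SE 0.17). Pericyte and smooth muscle markers had a median of -0.15, with 14 of 17 lower (adjusted p = 0.155), where Mylk gave -0.47 (SE 0.23) and Notch3 gave -0.33 (SE 0.17). It passed with normexp and without G2-EC-KO replicate 1 (median -0.36), while its direction turned without G2-EC-KO replicate 2 (median 0.086, adjusted p = 0.607), and leaving out 1 array moved Mylk between -0.75 and -0.18 and Notch3 between -0.51 and -0.15. Erythrocyte and platelet markers had a median of 0.43, with 8 of 9 higher (adjusted p = 0.103), where the platelet genes Gp9 and Ppbp gave 0.84 (SE 0.48) and 0.80 (SE 0.48). This list passed with normexp, without a filter on dim probes or with the deposited value table, without control replicate 2 (median 0.29) and without G2-EC-KO replicate 2 (median 0.89), while its direction turned without G2-EC-KO replicate 1 (median -0.026, adjusted p = 0.856). Leaving out 1 array moved Gp9 between 0.17 and 1.51 and Ppbp between 0.087 and 1.51. The extracellular matrix list had a median of 0.071 (adjusted p = 0.0948), where the collagen genes Col15a1 and Col18a1 gave 0.51 (SE 0.13) and 0.53 (SE 0.16). It passed without a filter on dim probes, without control replicate 2 (median 0.15) and without G2-EC-KO replicate 2 (median 0.12), while without control replicate 1 the median was 0.011 (adjusted p = 0.633). Angiocrine and cardioactive secreted factors had a median of 0.055 (limma camera, adjusted p = 0.489), where the cardiotrophin gene Ctf1 gave 0.73 (SE 0.12) and Wnt2 gave 0.55 (SE 0.16). With normexp Ctf1 gave 0.39 and Wnt2 gave 0.42.

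The remaining lists did not pass by limma camera on all arrays either. Medians were 0.12 for heat shock (adjusted p = 0.155), 0.14 for endothelial-to-mesenchymal transition (adjusted p = 0.321) and 0.079 for mesothelium and neural cells (adjusted p = 0.433). They were -0.032 for the BMP and TGF-beta pathway (adjusted p = 0.489), 0.032 for hypoxia response and glycolysis, -0.017 for the unfolded protein response, 0.072 for endothelial fatty acid uptake and lipid handling, 0.018 for immediate early and dissociation genes and -0.026 for haemostasis and vascular tone, the latter 5 with an adjusted p of 0.608. Interferon response had a median of -0.11 (adjusted p = 0.619), leukocyte adhesion and chemokines one of -0.041 and lymphocyte markers one of -0.11 (both adjusted p = 0.700). Apoptosis and p53 response had a median of 0.043 (adjusted p = 0.786), granulocyte markers one of 0.13 (adjusted p = 0.889), endothelial junctions and barrier one of 0.017 (adjusted p = 0.889), VEGF and angiogenic signalling one of -0.092 (adjusted p = 0.909) and axon guidance and semaphorins one of -0.023 (adjusted p = 0.931). Of the 30 lists that did not pass, 28 had a median that changed sign or moved by over 1.5 times when 1 array was left out, 21 of them in sign, and 12 passed without 1 of the arrays. Granulocyte and lymphocyte markers passed in opposite directions, higher without control replicate 1 (medians 0.50 and 0.24) and lower without control replicate 2 (medians -0.28 and -0.48). Interferon response passed as lower without control replicate 2 (median -0.28) or G2-EC-KO replicate 1 (median -0.24) and had medians of 0.037 without control replicate 1 and 0.066 without G2-EC-KO replicate 2. Leukocyte adhesion and chemokines passed as lower without G2-EC-KO replicate 1 (median -0.23), against 0.060 without G2-EC-KO replicate 2. Mesothelium and neural cells passed as higher without control replicate 1 (median 0.30), against -0.065 without control replicate 2, and endothelial-to-mesenchymal transition without G2-EC-KO replicate 2 (median 0.20), against -0.0052 without G2-EC-KO replicate 1. Heat shock passed without a filter on dim probes. The median, the mean and the direction of the camera test differed in sign for the unfolded protein response, venous endothelium, GATA family and partners, endothelial junctions and barrier, VEGF and angiogenic signalling, axon guidance and semaphorins, and endothelial identity.

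**Figure D3:**
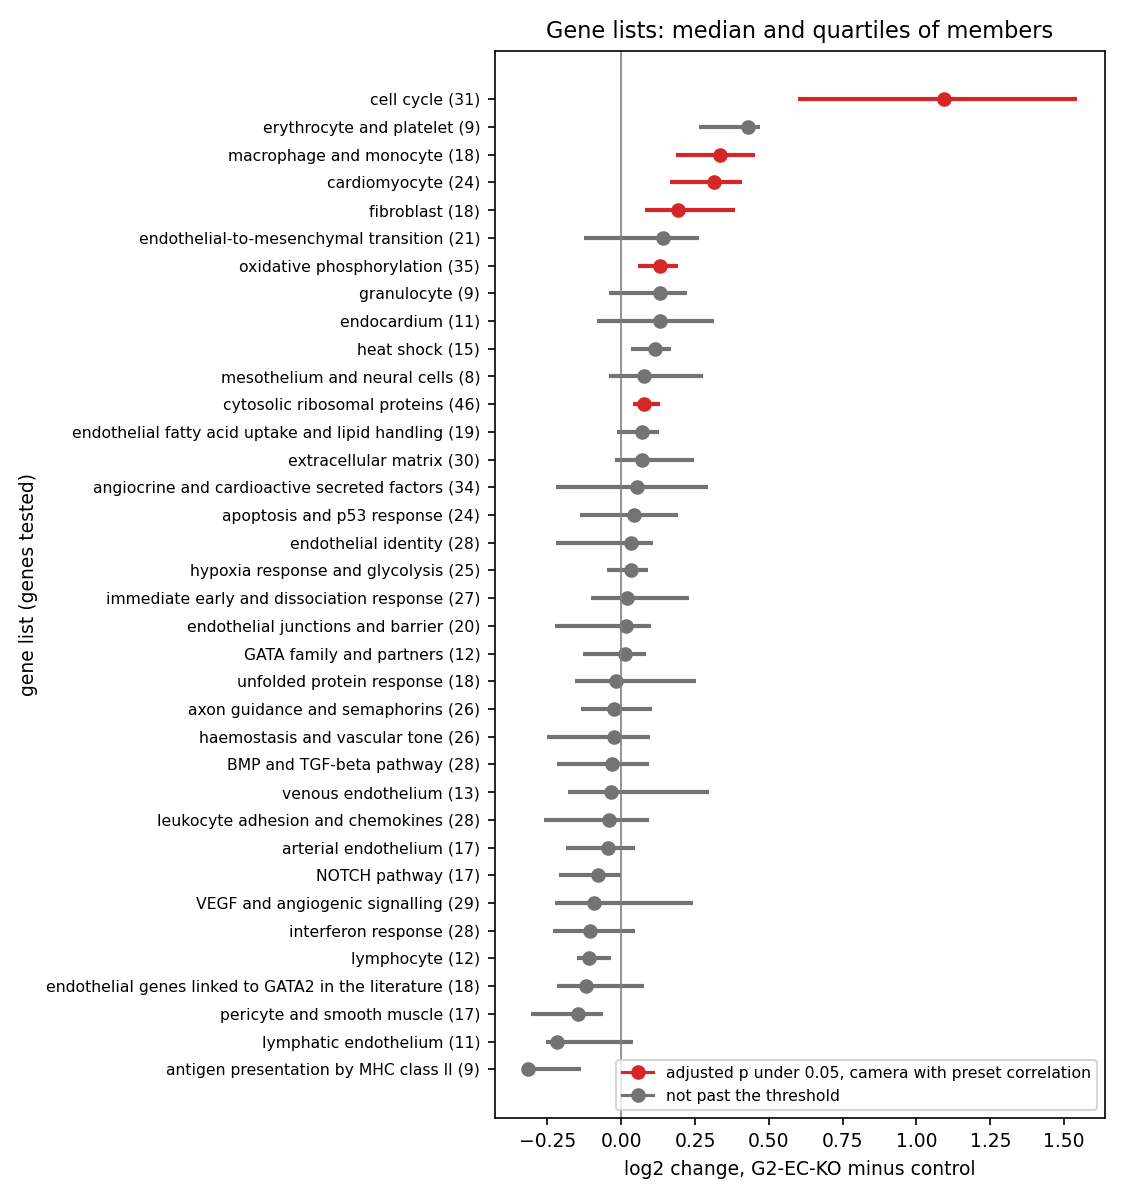
Median log2 change, G2-EC-KO minus control, of the measured genes of each of the 36 lists as points, with lines from the lower to the upper quartile of the genes and the number of genes in brackets. The 6 red lists have an adjusted p under 0.05 by camera with a preset correlation, and the cell cycle list lies farthest to the right, at 1.09.

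The control replicates differed from each other in sex-linked transcripts. Transcripts of the Y chromosome genes looked up, Ddx3y, Eif2s3y, Kdm5d and Uty, were well above background at 6 of 6 probes on control replicate 2. They were so at 0 on the other arrays. The X inactivation transcript Xist was well above background at 4 of 4 probes on the other 3 arrays and at 0 on control replicate 2. Sex was not part of the labels and could not be separated from leaving out control replicate 2, without which 0 probes and 12 lists, 8 higher and 4 lower, passed the threshold, and the cell cycle list had a median log2 change of 1.08.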

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

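All alternatives here were fixed before the data were examined. The 1 probe past the threshold became 2 with normexp (2 higher), quantile normalization, median centring and an adjusted p of 0.1 (1 higher and 1 lower in each), and 0 without a filter on dim probes, with the filter on all 4 arrays, with an intensity trend and with the replicate block. It stayed at 1 with the value table and with a log2 change of at least 1. Leaving out 1 array gave 0 to 8 probes and 0 to 3 genes with a symbol, the highest without control replicate 1, where control replicate 2 alone stands for control and Xist, Tsix and Ifi202b passed as higher. Each other array left out gave 0 probes. No gene with a symbol passed under any other alternative. The adjusted p of AK038629 ranged from 0.0206 to 0.243, with fitted log2 changes of 2.09 with normexp, 3.58 with the value table and up to 5.13, and that of AK037972 from 0.0155 to 0.584, and dim probes such as these have no value under the filter on all 4 arrays. NM_018852 passed with quantile normalization and median centring and ranged from 0.0402 to 0.397. At an unadjusted p under 0.05, normexp gave 1713 probes higher and 1063 lower, against 1317 and 1273.

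The 6 lists past the threshold became 0 with an estimated correlation and 0 with fry, and leaving out 1 array gave 6 to 12 lists, 12 without control replicate 2. Other settings gave 9 lists with normexp (6 higher and 3 lower, MHC class II, NOTCH, and pericyte and smooth muscle), 9 without the filter, 8 with the value table (7 and 1) and 7 with the filter on all arrays (6 and 1), the lower list being MHC class II in both, 7 with the replicate block, which adds the erythrocyte and platelet list, 6 with median centring and the trend, and 5 with quantile normalization. The cell cycle list passed under each setting of camera with the preset correlation, with medians of 0.88 to 1.49. Each of the other 5 called lists lost its call when at least 1 array was left out, and of 84 list values 62 kept direction and side of the threshold, 22 lost the call and 0 reversed. Gata2 ranged from 0.14 to 0.45 at its brighter probe and passed under no setting.

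The replicate numbers do not show a pairing: the deviations of same-numbered arrays correlated at 0.044 over 2 pairs. With the replicate block 0 probes and 7 lists passed, against 1 and 6 without it.

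Of 662 values of named genes, 636 kept direction and side, 4 newly passed, 6 no longer passed and 16 reversed, all of the latter in genes without a call. The cause was not tested. With quantile normalization Flt1 was -0.025 and Mmrn2 -0.020. Leaving out 1 array, Gata4 ranged from -0.34 to 0.038 at A_51_P492355 and from -0.048 to 0.094 at A_52_P4201, Gata6 from -0.055 to 0.27 at A_52_P176245 and from -0.27 to 0.75 at A_52_P590175, and Gata3 from -0.16 to 0.38. Likewise Lyz1 ranged from -0.12 to 0.42, Gsn from -0.065 to 0.24, Dcn from -0.15 to 0.39, Flt1 from -0.033 to 0.047 and Mmrn2 from -0.066 to 0.13. Where an array was left out, the lone array of its group was assumed to vary like the other group. Signal over background limits the folds of probes that were dim in a group, which are bounds.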

Other observations

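Outside the lists, some transcripts were not well above background on 1 of the control arrays. Ifi202b, an interferon-inducible gene, read -6.20 on control replicate 2, where it was not well above background, against 2.78 on control replicate 1 and 2.90 and 2.32 on the G2-EC-KO arrays. The peptide transporter gene Slc15a2 read -7.59 on control replicate 1, not well above background, against 1.15 on control replicate 2 and -0.16 and -0.48 on the G2-EC-KO arrays. Both were chosen after their values were seen.

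The tests that follow were chosen after the results were seen, except the count of lists in other groupings of the arrays. The wording of the explanation by exchanged arrays was also narrowed, from any wrong label to an exchange between the groups, after its value was known, and leaving out arrays was added to the leukocyte comparison after its value was known.

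The 4 arrays make 3 groupings into pairs, too few for a share under 0.05. The labelled grouping called 1 probe, as many were called in 2 of the 3 groupings, and the highest other count was 3. It called 6 lists, as many were called in 3 of the 3 groupings, and the highest other count was 14, in the grouping of control replicate 1 with G2-EC-KO replicate 2. At an unadjusted p under 0.05 the labelled grouping gave 2590 probes and the others 882 and 557.

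The cell cycle list was higher in G2-EC-KO. It was not called in either of the other groupings, but there a difference between the labels widens the spread within each pair. That result therefore lends it no support. The sex or another peculiarity of control replicate 2 as the whole cause of the higher cell cycle list is argued against. Without that array the median was 1.08, and the control arrays differ by 0.25 in these genes. More leukocytes with an unchanged share of cycling cells stay open. The highest median among the 3 leukocyte lists, with the SD among its genes, was set against the cell cycle median. With all arrays it was that of macrophage and monocyte markers, 0.34 (SD 0.38) against 1.09. The same list was highest without control replicate 2, at 0.65 (SD 0.51) against 1.08, and without G2-EC-KO replicate 1, at 0.32 (SD 0.41) against 1.49. Granulocyte markers were highest without control replicate 1, at 0.50 (SD 0.59) against 1.20, and without G2-EC-KO replicate 2, at 0.48 (SD 0.47) against 0.88. The gap was under the SD without control replicate 2 and without G2-EC-KO replicate 2. The SD among genes is not the error of a median. Cells of any kind that cycle more, endothelial or other, stay open, as do position on the slide, which follows the groups, and the knock out that the labels name, untested. The G2-EC-KO arrays differ by a median of 0.66, with 26 of 31 genes higher on replicate 2.

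Gata2 signal was not lower in the arrays labelled as its knock out. An exchange of arrays between the groups would leave at least 1 array low at probes that read the deleted part, and the largest difference between any 2 arrays at a Gata2 probe was 0.60 on the log2 scale. Correct labels would leave arrays low at such probes too, so this value cannot tell an exchange from correct labels. Probes outside the deleted part could give the same values, and this stays open, because the position in the transcript is given for 0 of the 2 probes. Cells in which the gene was not deleted stay open too, untested.

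Control replicates differed in Xist and Y-linked transcripts. A candidate explanation is that control replicate 2 is from a male and the other 3 from females, as Y-linked probes were well above background on control replicate 2 alone at 6 of 6 probes. Female RNA mixed into that array is argued against, as 0 Xist probes were well above background on it. No biological explanation by group was tested, since the labels give no sex.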
